A study of Mus musculus with 4 samples.

How the data were processed

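Gene expression was measured by droplet single-cell RNA sequencing of the 3' end in 4 mixed cultures of mouse BMDMs, 1 library per group: GFP+ WT cells with WT or with N4bp1 KO cells, unstimulated or stimulated through TLR7 for 8 h. Per the labels, cells were grown with 50 ng/ml M-CSF, replated on day 5 at 50% of each kind and cultured for 2 further days, with a stated target of 7000 cells per library. The TLR7 ligand, the deleted part of N4bp1 and the aligner are not given in the sources used here.

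The deposited values are raw counts, UMIs per gene and droplet, which the authors left unfiltered for cells and not normalized; per the file headers, Cell Ranger 4 wrote them. The submitters' processing notes name Cell Ranger 6.0.1, Seurat 4.0.4 and the builds GRCm38 and mm10. Each library lists 6794880 droplets and 52637 features, 1 of them the eGFP reporter, and 52489 features were matched to GENCODE M21. Unfiltered counts alone were used, and reads were not analysed here.

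The libraries hold 89753214 (WT unstimulated), 132670369 (KO unstimulated), 202807778 (WT stimulated) and 224219344 (KO stimulated) UMIs. A droplet was called a cell with at least 10% of the 99th percentile of UMIs among the top 7000 droplets, at least 500 genes and at most 20% mitochondrial UMIs. The UMI thresholds came to 10636, 8157, 4861 and 3169.7, and the cells called to 1742, 3914, 10628 and 19039, against the target of 7000 each. The automatic doublet call of Scrublet (scanpy 1.11.5) marked 1, 2, 1 and 1 cells and has not worked. The cells with the highest scores were therefore removed at a fixed rate of 0.8% per 1000 cells called: 24, 123, 904 and 2900 cells. The cells used have a median of 39798, 27105, 15564 and 9153 UMIs and 6571, 5700, 4056 and 3009 genes.

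Cells were divided into GFP- and GFP+ by Otsu's threshold on log2(1 + eGFP UMIs per 10000 UMIs), found for each library. Cells within 1 log2 unit of it number 475, 1037, 1639 and 4622 (27.6, 27.4, 16.9 and 28.6%). GFP- and GFP+ cells number 916 and 802, 1929 and 1862, 4713 and 5011, and 8914 and 7225.

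UMIs were summed over the cells of each of the 8 populations and expressed as CPM. A ratio of 2 populations has an exact 95% interval (conditional binomial, Clopper-Pearson) and a ratio of ratios one from Poisson error on the log scale. With 1 library per group these cover counting error only, not differences between cultures, mice or single cells, and no p-value was computed. A gene counts as measured with at least 30 UMIs and 5 CPM in the higher population. Higher and lower mean at least 1.5-fold. A population with 0 UMIs was set to a floor of 3 UMIs and the ratio given as a bound. Shares of cells with a transcript were counted after each cell was thinned to 6000 UMIs, and cells below that depth were left out. Intervals of these shares and of GFP+ shares are exact binomial over the cells of 1 library, and do not cover differences between cultures. The share that free RNA alone would mark was computed, after seeing the data, from the profile of droplets of 1 to 50 UMIs and the reporter level in GFP- cells, which overstates it where misassigned GFP+ cells add to that level. The 15 gene lists were fixed before the data were examined. Each list is described by its members higher and lower and by the percentile of its median log2 ratio among 10000 random lists of equal size drawn from the 100 genes nearest in level to each member. The random genes were drawn independently, while members of a list can vary together. A percentile therefore describes these libraries and does not measure differences between cultures.

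Genes were named by a rule fixed at the same time: the 10 highest and 10 lowest ratios among genes with at least 100 UMIs and 20 CPM in the higher population for the WT response to TLR7 and for KO over WT with and without stimulation, and 5 of each for other comparisons. Also named are the 4 members of each list with the largest absolute log2 ratio, and N4bp1, Tnf, Il6, Il12b, Il1b, Nfkbia, Tnfaip3, Ikbke, Tbk1 and Casp8 in every comparison. The rule leaves out the reporter, sex-linked genes, the genes Nnt, Wdfy1, Ide and Entpd4, which can differ between donor mice, and predicted genes named by number (Gm or Rik). One gene that the rule picks for stimulated KO over WT cells is not reported here.

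Cells of all libraries were clustered (scanpy 1.11.5, leidenalg 0.10.2) on 2000 variable genes, 30 components and 15 neighbours at resolution 0.60, only to find other cell types. Of 12 clusters, 3 were led by markers of other cell types. A run on macrophage-like clusters alone, planned in advance, was made by leaving out these 3 clusters. The other settings planned in advance were a minimum of 1000 UMIs per droplet, at most 10% mitochondrial UMIs, no doublets removed, a reporter threshold of 1 UMI, cells near the reporter threshold left out, ambient RNA subtracted with the profile of droplets of 1 to 50 UMIs, TMM scaling (edgeR 4.0.16, R 4.3.3), the mean of per-cell CPM, each cell thinned to one depth, no filter on low counts, and a 2-fold rule. A further setting, each gene without the largest single cell of each population, was chosen after seeing the data.

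The steps were tested on simulated data made from the stimulated KO and WT populations with known folds set in some of 9251 genes. Counts were drawn as Poisson totals per population, the model behind the intervals. The simulation therefore checks the calculation, and leaves out UMIs gathered in single cells. Folds of 1.5, 2 and 4 were recovered as 1.5, 2.0 and 4.03, and the interval covered 1 in 94.6% of genes with no difference, none of which passed 1.5-fold. The interval covered the true fold in 98.5, 87.9 and 90.9% of genes, and 47% of genes with a true fold of 1.5 passed 1.5-fold. The same folds came back as 1.5, 1.99 and 3.99 in the ratio of ratios. In simulated reporter counts at the depth of each library 1.4, 1.66, 0.864 and 8.46% of cells were assigned to the wrong side. The simulation gave all GFP- cells of a library 1 reporter rate and GFP+ cells a fixed relative spread. Both rates were those of the populations already divided at the threshold, so cells misplaced there are not represented. Real cells may vary more, so these are error rates of the simulation and not of the data. Calculations used python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9. Shares of cells in the 3 clusters led by other cell types are given as a description, with intervals over the cells of 1 library, and were not tested. Sizes of the other clusters and the genes that define clusters were not compared between groups, because cells of 1 library are not replicates.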

Results

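Macrophages grown from mouse bone marrow (BMDMs) that lacked N4bp1, or wild-type (WT) counterparts, were mixed with GFP+ WT BMDMs at 50% each, left unstimulated or stimulated through TLR7 for 8 h, and profiled as 4 single-cell libraries, 1 per group. N4bp1 encodes an RNA-binding protein known to restrain inflammatory signalling. The cells used were 1718 (WT unstimulated), 3791 (KO unstimulated), 9724 (WT stimulated) and 16139 (KO stimulated), and the reporter divided each library into a GFP- and a GFP+ population. Below, WT cells and KO cells are the GFP- populations, and GFP+ cells are the WT neighbours grown with them. Each group is 1 library, and no test across cultures was made. Values in brackets after a gene are the ratio of UMIs per 1000000 (CPM) and its 95% interval for counting error only, and higher and lower mean at least 1.5-fold between these libraries.

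GFP+ cells made up 46.7% (95% interval 44.3 to 49.1%) of the unstimulated culture with WT cells and 49.1% (47.5 to 50.7%) of that with KO cells. After stimulation they made up 51.5% (50.5 to 52.5%) and 44.8% (44 to 45.5%). Reporter transcripts in GFP+ cells stood at 852, 858, 1383 and 490.4 CPM in the same order, and in GFP- cells at 27.9, 26.7, 24.3 and 16.9 CPM. In simulated cells at the depth of the stimulated KO library 8.46% were assigned to the wrong side, and a true GFP+ share of 49.7% was read as 43.4%. The simulated reporter rates came from the populations as divided here, so the error rate of the real cells is not known.

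**Figure D1:**
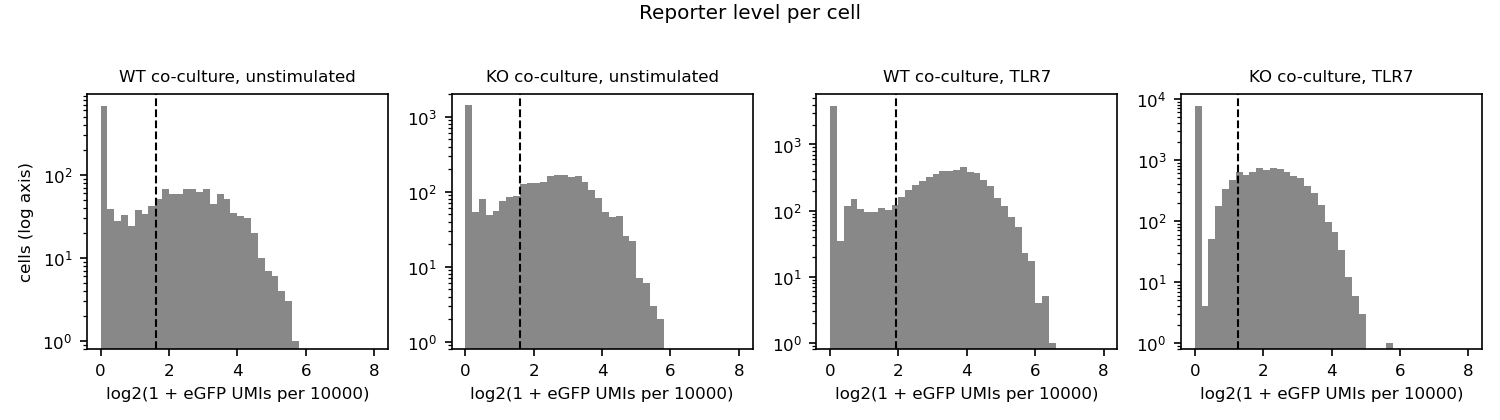
Number of cells (log axis) by log2(1 + eGFP UMIs per 10000 UMIs of the cell) in each of the 4 libraries, with the GFP-/GFP+ threshold of each library as a dashed line. The cells within 1 log2 unit of the threshold number 475, 1037, 1639 and 4622.

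N4bp1 transcripts themselves stood at 49.9 CPM in unstimulated WT cells and 66.6 CPM in unstimulated KO cells, and at 266 and 397 CPM after stimulation (KO over WT 1.34, 1.27 to 1.41 unstimulated; 1.49, 1.47 to 1.52 stimulated). GFP+ cells held 52.7 and 53.1 CPM unstimulated, and 274 and 333 CPM stimulated, beside WT and KO cells in turn. N4bp1 was higher after stimulation in WT cells (5.33, 5.1 to 5.58) and in KO cells (5.95, 5.76 to 6.16). The tags sit at the 3' end of a transcript, which may lie outside the deleted part, so these counts neither show nor exclude loss of the protein.

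TLR7 stimulation of WT cells was marked by far more transcripts of secreted and effector genes and fewer of cell-cycle genes. The largest ratios, stimulated over unstimulated, were those of the scavenger receptor Marco (7181, 1289 to 283657), with 1 UMI in unstimulated cells, the acute-phase gene Saa3 (2396, 2154 to 2673) and the itaconate-producing enzyme Acod1 (1804, 1075 to 3300.3). Nitric oxide synthase Nos2, with 0 UMIs unstimulated, was at least 1648-fold higher. Tarm1 (1352, 374 to 11168), lysyl oxidase Lox (1308, 235 to 51682) and endothelin Edn1 (1061, 294 to 8767) came next. They were followed by the formyl peptide receptors Fpr1 (451, 219 to 1123) and Fpr3 (441, 202 to 1201) and the signalling inhibitor Socs3 (399, 281 to 587). The lowest were the transporter Slco2b1 (0.0051, 0.00285 to 0.00844), Rasgrp3 (0.00527, 0.00385 to 0.00704), Cd28 (0.00625, 0.00446 to 0.00853) and Sox4 (0.0063, 0.00372 to 0.0100). Next lowest were Zbtb16 (0.00869, 0.00484 to 0.0144), Samd4 (0.00883, 0.00594 to 0.0127) and the chemokine receptor Cxcr4 (0.0115, 0.00914 to 0.0143). Shisa9 (0.012, 0.0089 to 0.0158), the prostaglandin-degrading enzyme Hpgd (0.0144, 0.0115 to 0.0177) and Fam214a (0.0197, 0.0163 to 0.0237) were lower too. The cytokines Tnf (12.2, 11.3 to 13.2), Il1b (155, 123 to 197) and Il6 (78.2, 26.6 to 381) were higher, and Il12b was at least 212-fold higher. The feedback inhibitors Nfkbia (10.7, 10.3 to 11) and Tnfaip3 (5.56, 5.09 to 6.08) and the kinase Ikbke (5.54, 5.29 to 5.81) were also higher. Tbk1 (1.16, 1.12 to 1.2) and Casp8 (1.46, 1.4 to 1.52) lay within 1.5-fold.

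Of the gene lists, cytokines (12 of 12 higher and 0 lower), metabolic and effector genes (19 of 19 higher and 0 lower) and interferon-stimulated genes (39 of 39 higher and 0 lower) were higher in every measured member. Their median log2 ratios were 4.93, 2.40 and 2.84, with Ptges (278, 183 to 443), Slfn4 (56.4, 37.8 to 88.2) and Rsad2 (25.4, 24.4 to 26.4) among the members. Chemokines (14 of 15 higher and 1 lower), NF-kB subunits and feedback targets (19 of 25 higher and 2 lower) and the IKK-related kinases and adaptors (5 of 10 higher and 0 lower) followed. Examples are Ccl5 (344, 299 to 397), Sod2 (26.3, 25.4 to 27.3) and Optn (3.17, 2.88 to 3.48). Antigen presentation genes (8 of 17 higher and 1 lower) included Cd274 (23.2, 21.6 to 24.9), the gene of PD-L1. Cell-cycle genes were low (0 of 22 higher and 18 lower), with Mcm2 (0.188, 0.166 to 0.212) and Rrm2 (0.189, 0.172 to 0.209). The median of all measured genes stood at -0.35 log2, and TMM scaling shifts every ratio by 0.37, so lists with small medians depend on the scaling. Resting-macrophage genes had 5 of 21 higher and 11 lower (5 higher and 7 lower with TMM scaling), with Cx3cr1 (0.21, 0.20 to 0.221) and Mertk (0.35, 0.333 to 0.369). Cell-death genes had 11 of 20 higher and 3 lower (12 higher and 1 lower with TMM scaling), with the death receptor Fas (5.74, 5.1 to 6.48). TLR pathway genes had 7 of 23 higher and 3 lower (9 higher and 2 lower with TMM scaling), with the negative regulator Irak3 (8.69, 8.24 to 9.16). Cholesterol genes had 1 of 18 higher and 1 lower (12 higher and 0 lower with TMM scaling), and RNA-decay genes 5 of 13 higher and 3 lower (6 higher and 2 lower with TMM scaling), with Zfp36l1 (0.153, 0.147 to 0.16). Stress and RNA-quality genes had 1 of 11 higher and 3 lower (5 higher and 0 lower with TMM scaling), with Malat1 (0.517, 0.515 to 0.519) and mt-Atp6 (0.618, 0.603 to 0.633). Early-response genes had 6 of 20 higher and 6 lower, with Dusp2 (31.8, 26.6 to 38.2) and Egr2 (0.106, 0.0816 to 0.136). Marco, Tarm1, Lox, Edn1 and Il6 rest on 1 to 3 unstimulated UMIs, so their size is known only within the wide intervals given. With each cell thinned to 6000 UMIs, Ccl5 stood at 211, Il1b at 260.3 and Slfn4 at 36.6. Fpr1 stood at 144 with a minimum of 1000 UMIs per droplet. Acod1 stood at 2934 with a reporter threshold of 1 UMI and 1141 as a mean of per-cell CPM. Thinned values on the lower side were Rasgrp3 0.00345, Samd4 0.00327, Hpgd 0.00598 and Egr2 0.0633. Without clusters led by other cell types, Sox4 stood at 0.00248, Cxcr4 at 0.00598 and Hpgd at 0.00383.

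In KO cells, too, stimulation through TLR7 came with more transcripts of secreted and effector genes. Of the lists, 14 of 14 cytokines, 20 of 20 metabolic genes and 39 of 39 interferon-stimulated genes were higher than in unstimulated KO cells. So were 14 of 16 chemokines and 21 of 25 NF-kB genes. The largest ratios were Il1b (4381, 2968 to 6769.9), Edn1 (3141, 869 to 25942), with 2 UMIs in unstimulated cells, and Marco (2059.8, 999.6 to 5124). The granulocyte growth factor Csf3, with 0 UMIs in unstimulated cells like the next 3 genes, was at least 1943-fold higher and U90926 at least 1508-fold higher. Il6 was at least 1152-fold and Il12b at least 1209-fold higher, beside Tnf (35.4, 33.3 to 37.7), Tnfaip3 (23.3, 21.6 to 25.1), Nfkbia (12.4, 12.1 to 12.8) and Ikbke (4.81, 4.64 to 5.0). Tbk1 (1.23, 1.19 to 1.27) and Casp8 (1.23, 1.19 to 1.28) lay within 1.5-fold. The lowest were Slco2b1, with a ratio of 0.00036 from 1 stimulated UMI, Rasgrp3 (0.00215, 0.00125 to 0.00344), Hpgd (0.00223, 0.00136 to 0.00345), Cd28 (0.00338, 0.00214 to 0.00507) and Zbtb16 (0.0054, 0.00269 to 0.00969). Cell-cycle genes had 0 of 22 higher and 19 lower, and the kinases and adaptors of the IKK list 6 of 10 higher and 0 lower (9 higher and 0 lower with TMM scaling). The median of all genes stood at -0.43 log2 and TMM scaling adds 0.47. It moves the splits of TLR pathway genes (8 of 23 higher and 7 lower, 9 higher and 5 lower with TMM scaling) and cell-death genes (9 of 20 higher and 3 lower, 12 higher and 2 lower with TMM scaling). Early-response genes had 6 of 20 higher and 7 lower (10 higher and 5 lower with TMM scaling) and RNA-decay genes 5 of 13 higher and 4 lower (5 higher and 2 lower with TMM scaling). Antigen presentation genes had 8 of 18 higher and 5 lower (9 higher and 2 lower with TMM scaling) and resting-macrophage genes 4 of 21 higher and 13 lower (5 higher and 9 lower with TMM scaling). Cholesterol genes had 1 of 18 higher and 2 lower (6 higher and 2 lower with TMM scaling), and stress genes 6 of 12 higher and 3 lower (7 higher and 2 lower with TMM scaling). With a reporter threshold of 1 UMI Il1b stood at 7679 and Zbtb16 at 0.00299, and Edn1 at 1795 as a mean of per-cell CPM.

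Without stimulation, KO and WT cells differed in few genes. Lower in KO cells were the chemokines Ccl7 (0.273, 0.252 to 0.295), Ccl2 (0.391, 0.374 to 0.408) and Ccl8 (0.483, 0.431 to 0.541), the urokinase gene Plau (0.429, 0.404 to 0.455) and osteopontin Spp1 (0.608, 0.604 to 0.612). Pdpn (0.574, 0.526 to 0.627), Gdf15 (0.623, 0.566 to 0.686) and Nptx1 (0.494, 0.459 to 0.531) were lower as well. So were Ctnnd2 (0.564, 0.523 to 0.608), Chst11 (0.611, 0.582 to 0.643) and AC133083.2 (0.613, 0.563 to 0.667). Higher were Saa3 (6.4, 5.72 to 7.18), the membrane genes Tmem176a (1.83, 1.71 to 1.95) and Tmem176b (1.81, 1.74 to 1.88), and Dennd2a (1.91, 1.73 to 2.11). Pla2g7 (1.81, 1.69 to 1.95), the integrin Itgal (1.75, 1.59 to 1.92), the pseudogenes Tpt1-ps3 (2.48, 2.24 to 2.74) and Rpl3-ps1 (1.74, 1.59 to 1.91), and the neutrophil granule genes Ltf (2.03, 1.84 to 2.26) and Lcn2 (1.96, 1.81 to 2.13) were higher too. The neutrophil markers S100a8 (307 CPM in KO against 204 CPM in WT cells) and S100a9 (386 against 235 CPM) lay on the same side, and Elane (1.86 against 3.05 CPM) on the other. Clusters led by other cell types held 0.985% of KO and 0.546% of WT cells. Il1b stood at 0.438 against 1.79 CPM, below the 5 CPM at which a gene counts as measured. Tnf (1.05, 0.956 to 1.16), Nfkbia (1.19, 1.14 to 1.24), Tnfaip3 (0.978, 0.873 to 1.1), Ikbke (1.16, 1.1 to 1.23), Tbk1 (1.03, 0.988 to 1.07) and Casp8 (1.04, 0.989 to 1.08) lay within 1.5-fold. Il6 and Il12b had too few UMIs for a ratio.

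Among the lists, chemokines had 1 of 13 higher and 5 lower, NF-kB genes 1 of 24 higher and 0 lower with Traf1 (1.73, 1.44 to 2.09), and stress genes 0 of 11 higher and 1 lower with mt-Atp6 (0.635, 0.619 to 0.652). No measured member of the other 12 lists was higher or lower. NF-kB genes leaned up (21 of 24 above the median of all genes; percentile 100.0), as did RNA-decay (10 of 12; percentile 99.6) and antigen presentation genes (13 of 17; percentile 99.8). Interferon-stimulated (28 of 36 below; percentile 0.010), cell-cycle (16 of 22; percentile 0) and stress genes (8 of 11; percentile 1.11) leaned down. Such percentiles leave out that members of a list can vary together, and cannot tell genotype from another difference between the cultures. The higher chemokine was Ccl5 (2.12, 1.8 to 2.5), which stood at 1.12 in thinned cells and 1.06 as a mean of per-cell CPM. A single cell held 36.4% of the UMIs of Saa3 in the higher population, and the ratio stood at 3.37 in thinned cells and 10.7 with a reporter threshold of 1 UMI. Without clusters led by other cell types Ltf stood at 1.09 and Lcn2 at 15.7, the latter over 3 WT UMIs, and in thinned cells at 3.52 and 3.33. Ccl7 stood at 0.534 with a reporter threshold of 1 UMI.

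After TLR7 stimulation, KO cells held more transcripts of most inflammatory cytokines and of part of the effector and NF-kB feedback genes than WT cells. Cytokines had 10 of 14 higher and 0 lower, with a median log2 ratio of 1.83, at percentile 100.0 of random lists of equal size and level. They include Il6 (10.7, 9.68 to 11.7), Il1a (10.1, 9.2 to 11.2), Csf3 (7.77, 7.29 to 8.29), Il12b (4.13, 3.88 to 4.39) and Tnfsf15 (8.77, 6.72 to 11.6), the last at 5.31 in thinned cells. Il1b (6.91, 6.82 to 7.01) stood at 1918 against 277 CPM and Tnf (3.05, 3.0 to 3.11) at 644 against 211 CPM. Chemokines divided (6 of 16 higher and 4 lower): Cxcl1 (14.3, 13.4 to 15.3), Cxcl2 (9.91, 9.71 to 10.1), Cxcl3 (9.06, 8.0 to 10.3) and Ccl3 (2.88, 2.85 to 2.9) were higher, and Ccl2 was lower (635 against 1236 CPM). Metabolic and effector genes (11 of 20 higher and 0 lower, percentile 100.0) were led by the prostaglandin synthase Ptgs2 (13.1, 12.7 to 13.5), the cystine transporter Slc7a11 (11.7, 11 to 12.4), the arginine transporter Slc7a2 (7.66, 7.39 to 7.93) and Nos2 (3.38, 3.3 to 3.46). NF-kB subunits and feedback genes stood in the same direction (10 of 25 higher and 0 lower, percentile 100.0), with Tnfaip3 (4.1, 3.98 to 4.22), Traf1 (3.52, 3.34 to 3.72), Tnfaip2 (2.15, 2.1 to 2.21) and Nfkbie (2.1, 1.96 to 2.26). The inflammasome sensor Nlrp3 (3.36, 3.27 to 3.45) and Tank (1.63, 1.6 to 1.66) were higher too. Other high ratios were those of U90926 (11.4, 10.5 to 12.5) and AC121583.1 (15.3, 13.3 to 17.7). Within 1.5-fold lay Nfkbia (1.38, 1.37 to 1.4), Ikbke (1.01, 0.989 to 1.03), Tbk1 (1.09, 1.07 to 1.12) and Casp8 (0.874, 0.849 to 0.901).

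Interferon-stimulated, cholesterol, resting-macrophage and cell-cycle genes had medians below those of matched lists, with few members lower. Interferon-stimulated genes had 1 of 39 higher and 9 lower (2 higher and 7 lower with TMM scaling), with Ifit2 (0.356, 0.35 to 0.362), Ifit3b (0.427, 0.401 to 0.453) and Ifit3 (0.44, 0.431 to 0.45) lower and Ifi205 (1.91, 1.85 to 1.97) higher. Their median of -0.31 log2 lies at percentile 0. Cholesterol genes had 0 of 18 higher and 4 lower (0 higher and 2 lower with TMM scaling; percentile 0), with Abcg1 (0.488, 0.463 to 0.514). Resting-macrophage genes had 0 of 21 higher and 4 lower (0 higher and 3 lower with TMM scaling; percentile 0), with Mertk (0.446, 0.417 to 0.478) and Fcgr1 (0.559, 0.552 to 0.567). Cell-cycle genes had 0 of 21 higher and 2 lower (0 higher and 1 lower with TMM scaling; percentile 0.040), with Hist1h1b (0.60, 0.561 to 0.642). TLR pathway genes had 0 of 23 higher and 4 lower, with the transcription factor Irf5 (0.444, 0.429 to 0.461) and the receptor Tlr4 (0.551, 0.53 to 0.572). RNA-decay genes had 0 of 13 higher and 3 lower (1 higher and 2 lower with TMM scaling), with Zfp36l2 (0.571, 0.538 to 0.606). Cell-death genes had 2 of 20 higher and 2 lower (2 higher and 0 lower with TMM scaling), with Fas (2.0, 1.92 to 2.09). Early-response genes had 7 of 17 higher and 4 lower (7 higher and 2 lower with TMM scaling), with Egr1 (3.33, 2.82 to 3.94). Antigen presentation genes had 2 of 17 higher and 1 lower (2 higher and 0 lower with TMM scaling), with H2-Ab1 (1.78, 1.68 to 1.88), and the IKK list 1 of 10 higher and 0 lower. The lowest single genes included the growth factor Pdgfc (0.223, 0.202 to 0.247), Fat3 (0.198, 0.185 to 0.212), Adra1a (0.227, 0.21 to 0.246) and cyclin D1 Ccnd1 (0.233, 0.22 to 0.247). Nfatc2 (0.274, 0.254 to 0.296) and the receptor Cd180 (0.283, 0.273 to 0.293) were lower too. Also among the lowest were Tpt1-ps3 (0.164, 0.146 to 0.183), Mir6236 (0.196, 0.184 to 0.209), Rps10-ps2 (0.26, 0.237 to 0.284) and Gpx4 (0.273, 0.26 to 0.286). The last 4 were as low in GFP+ cells of the same library (0.188, 0.245, 0.273 and 0.291). Of the stress and RNA-quality genes (2 of 12 higher and 1 lower), mt-Atp6 (1.92, 1.88 to 1.95) was as high there (2.0). The immunoglobulin gene Igkc (129.5, 96.7 to 178) was the highest of all, but 1 cell held 65.6% of its UMIs. The Igkc ratio stood at 80.2 without the largest cell of both populations, 27.3 with a minimum of 1000 UMIs per droplet and 972 without clusters led by other cell types. Clusters led by other cell types held 2.34% of stimulated KO and 1.72% of stimulated WT cells. Of the neutrophil markers S100a8 stood at 649.6 against 296 CPM, but S100a9 at 249 against 215, Csf3r at 186 against 174 and Mpo at 1.76 against 2.97 CPM. Osteoclast-like cells made up 0.931% (0.742 to 1.15%) of KO and 0.424% (0.259 to 0.655%) of WT cells, with Acp5 at 58.9 against 39.8 and Mmp9 at 41.9 against 26.7 CPM, but Ctsk at 10.3 against 12.6 CPM. Of the monocyte markers Hp stood at 473 against 165 and Ly6c2 at 35.7 against 19.8 CPM, but Ccr2 at 33.2 against 64.3 and Plac8 at 13.4 against 20.4 CPM. Without clusters led by other cell types 10 cytokines were higher, as many as with them. TMM scaling adds 0.10 log2 to every ratio.

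**Figure D2:**
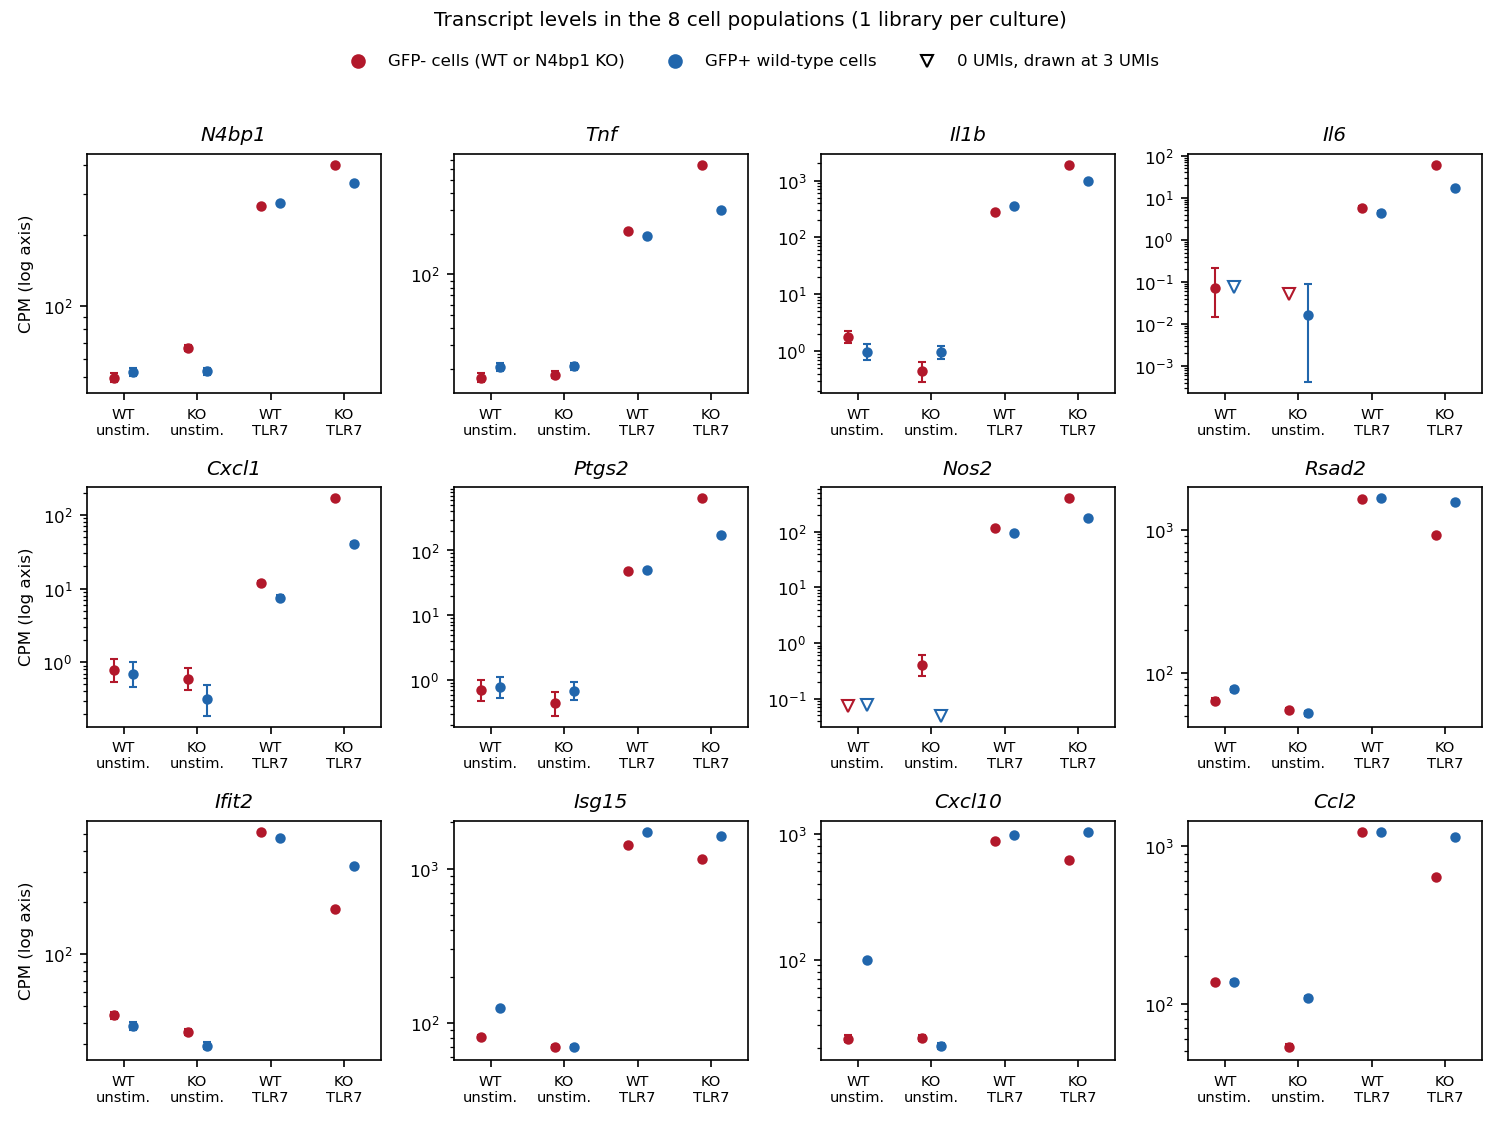
Level of 12 genes in CPM (log axis) in the 4 libraries, GFP- cells in red and GFP+ cells in blue; bars are 95% intervals for counting error and open triangles mark 0 UMIs drawn at the level of 3 UMIs. After stimulation Tnf, Il1b, Il6, Cxcl1, Ptgs2 and Nos2 are higher in KO than in WT GFP- cells (Ptgs2 642 against 49.1 CPM), and Ifit2 is lower (182 against 512 CPM).

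Tnf, Il6, Il12b and Nos2 transcripts were found in a larger share of stimulated KO than WT cells, beyond what free RNA would give. Each cell was thinned to 6000 UMIs, of which free RNA made up an estimated 7.23% in the stimulated KO and 3.46% in the stimulated WT library. Intervals of shares are over the cells of 1 library and do not cover differences between cultures. Tnf was found in 76.1% (75.1 to 77%; 82% before thinning) of KO and 50.4% (48.9 to 51.8%; 69.3% before thinning) of WT cells, where free RNA alone would mark 18.3% and 4.18%. Il6 was found in 17.6% (16.8 to 18.5%; 23% before thinning) and 2.57% (2.13 to 3.08%; 5.79% before thinning) (free RNA 1.91% and 0.0953%). For Il12b the shares were 12.4% (11.6 to 13.1%; 14.6% before thinning) and 4.73% (4.13 to 5.39%; 8.42% before thinning) (free RNA 1.37% and 0.171%). Nos2 was found in 49.3% (48.1 to 50.4%; 53.2% before thinning) and 20.9% (19.8 to 22.1%; 31.2% before thinning) (free RNA 10.6% and 2.12%). Il1b was found in 74.6% (73.6 to 75.6%; 78.3% before thinning) and 33.3% (32 to 34.7%; 44.8% before thinning), but free RNA alone would mark 47.8% and 7.17%. With it removed 51.4% and 28.2% remain. Ccl5 shares (85.6% and 74.4%) stand beside a free-RNA share of 74.8% and 35%, and are not read as a difference. The interferon-stimulated gene Ifit1 was found in 83.1% (82.3 to 84%, 87.9% before thinning) of KO and 90.1% (89.2 to 90.9%, 95.9% before thinning) of WT cells (free RNA 32.1% and 19.2%), and Cxcl10 in 39.5% (38.4 to 40.6%, 46.2% before thinning) and 44.6% (43.1 to 46%, 58.5% before thinning) (free RNA 30.2% and 19.8%). With this estimate of free RNA removed, 75.2% and 87.7% remain for Ifit1 and 13.3% and 30.9% for Cxcl10. Osteoclast-like cells, GFP- and GFP+ together, held Il1b in 38.9% of 95 thinned cells of the stimulated KO and 3.57% of 28 of the stimulated WT library, no more than free RNA alone would mark. Tnf was found in 42.1% (32 to 52.7%) and 17.9% (6.06 to 36.9%) of these cells, above its free-RNA shares. Ccl5 was found in 55.8% (45.2 to 66%) of them in the KO library, below its free-RNA share of 74.8%, so the estimate may be too high in that library. In the WT library it was found in 28.6% (13.2 to 48.7%), an interval that covers its free-RNA share of 35%. In unstimulated WT and KO cells the thinned shares were 7.53% and 8.5% for Tnf, 0.546% and 0.156% for Il1b, and 13.1% and 12.6% for Ifit1. Il6 and Il12b were found in none of these thinned cells, and before thinning Il6 was found in 0.218% of unstimulated WT cells. The cells too shallow for thinning numbered 1548 stimulated KO and 166 stimulated WT cells, and 0 unstimulated cells.

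GFP+ WT cells beside KO cells held more transcripts of most cytokines and of part of the effector genes after stimulation than GFP+ cells beside WT cells, by smaller ratios. The highest were Cxcl1 (5.42, 4.98 to 5.9), Ptgs2 (3.43, 3.31 to 3.55), Csf3 (3.34, 3.12 to 3.59), Cxcl2 (3.2, 3.14 to 3.27) and Slc7a11 (2.93, 2.74 to 3.14). The cytokines Il6 (3.9, 3.47 to 4.38), Il1a (3.07, 2.76 to 3.42), Il1b (2.68, 2.64 to 2.71), Il12b (1.99, 1.83 to 2.16) and Tnf (1.56, 1.53 to 1.59) were higher. Tnfaip3 (1.98, 1.92 to 2.04) and Nlrp3 (2.04, 1.99 to 2.1) were higher too. Cytokines had 8 of 13 higher and 0 lower, metabolic genes 9 of 20 higher and 0 lower, NF-kB genes 4 of 25 higher and 1 lower and chemokines 3 of 15 higher and 0 lower. Interferon-stimulated genes had 1 of 39 higher and 0 lower, with a median of -0.09 log2 at percentile 1.0 and Ifit2 (0.687, 0.676 to 0.697), Ifit3 (0.741, 0.728 to 0.754) and Ifi205 (1.54, 1.5 to 1.59) among them. As in KO cells, cholesterol (17 of 18 below the median of all genes; percentile 0) and resting-macrophage genes (18 of 21; percentile 0.030) leaned down, and so did antigen presentation genes (11 of 16; percentile 0.47). The lowest were Tpt1-ps3 (0.188, 0.167 to 0.211), mt-Nd3 (0.208, 0.192 to 0.226), Mir6236 (0.245, 0.228 to 0.264), Rps10-ps2 (0.273, 0.249 to 0.299) and Gpx4 (0.291, 0.277 to 0.306). mt-Atp6 (2.0, 1.96 to 2.04) was higher. Nfkbia (1.16, 1.15 to 1.17), Ikbke (0.987, 0.968 to 1.01), Tbk1 (1.05, 1.02 to 1.08) and Casp8 (0.972, 0.944 to 1.0) lay within 1.5-fold. Thinned to 6000 UMIs, 60.5% (59.2 to 61.7%; 69.3% before thinning) of GFP+ cells beside KO cells and 48.2% (46.8 to 49.6%; 70.1% before thinning) of those beside WT cells held Tnf, where free RNA alone would mark 18.3% and 4.18%. With free RNA removed 51.6% and 45.9% remain for Tnf, and for Il6 4.32% and 2.04%. Il1b was held by 63.1% (61.9 to 64.3%, 69.7% before thinning) and 37% (35.6 to 38.3%, 49.3% before thinning), and with free RNA removed 29.4% and 32.1% remain. The free-RNA estimate may be too high in the KO library. Of its osteoclast-like cells 55.8% held Ccl5, where free RNA alone would mark 74.8%, although Tnf lay above the estimate (42.1% against 18.3%). Whether a larger share of cells held Il1b beside KO cells is therefore not decided. In turn 1026 and 84 cells were too shallow for thinning. Of the named genes only Cxcl3 (2.16, 1.91 to 2.45) moved by more than 1.5 times under an alternative, to 1.18 without the cells near the reporter threshold.

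In unstimulated cultures, GFP+ cells beside KO cells held fewer transcripts of part of the interferon-stimulated genes than those beside WT cells. That list had 0 of 36 higher and 5 lower, and 35 members lay below the median of all genes, with Isg20 (0.544, 0.471 to 0.629), Ifi44 (0.549, 0.476 to 0.634), Isg15 (0.566, 0.543 to 0.59) and Ifit3 (0.629, 0.592 to 0.669). Isg15 stood at 124 CPM in GFP+ cells beside WT cells, above GFP+ cells beside KO cells (70.4), WT cells (81.2) and KO cells (69.8). Ifit2 did not follow that order (38.3, 29.4, 44.3 and 35.4 CPM in turn). Cxcl10 (0.209, 0.196 to 0.223) was lower as well, with 38.5% of its UMIs in 1 cell of the higher population, as were Camp (0.259, 0.23 to 0.291) and Chil3 (0.578, 0.536 to 0.624), genes of granulocytes and monocytes, with 41.5% and 44.4% of UMIs in 1 cell. Other markers of these cells divided. Beside KO and beside WT cells in turn, S100a9 (250 and 284 CPM) and Ccr2 (111 and 119 CPM) lay on the same side. Elane (9.26 and 0.511 CPM), Mpo (6.29 and 0.205 CPM), Ly6c2 (8.91 and 3.12 CPM) and Plac8 (12.9 and 5.96 CPM) lay on the other. For Csmd1 (0.0171, 0.0106 to 0.026) 1 cell held 97.8% of the UMIs beside WT cells, and the ratio stood at 0.713 without the largest cell of both populations. The highest were Tpt1-ps3 (2.37, 2.15 to 2.61), mt-Nd3 (1.63, 1.56 to 1.69), Rps24-ps3 (1.61, 1.46 to 1.77), Sec61g (1.56, 1.42 to 1.72) and AC124744.2 (1.53, 1.42 to 1.67). Tnf (1.01, 0.92 to 1.1), Nfkbia (0.976, 0.936 to 1.02), Tnfaip3 (0.955, 0.848 to 1.08), Ikbke (1.01, 0.949 to 1.07), Tbk1 (0.968, 0.93 to 1.01) and Casp8 (0.982, 0.938 to 1.03) lay within 1.5-fold. Chemokines had 1 of 13 higher and 2 lower, and no measured member of the other 13 lists was higher or lower. Cxcl10 stood at 0.318 as a mean of per-cell CPM. Of the chemokines, Ccl5 (1.73, 1.54 to 1.95) stood at 0.516 with a minimum of 1000 UMIs per droplet and 0.315 without cells near the reporter threshold, and Ccl12 (0.374, 0.327 to 0.428) at 0.884 without the largest cell of both populations.

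Relative to the GFP+ cells of the same library, which shared medium, stimulation and sequencing, stimulated KO cells kept higher transcripts of most cytokines and lower transcripts of part of the interferon-stimulated genes. In this ratio of ratios cytokines had 9 of 14 higher and 0 lower (median 1.02 log2), metabolic genes 9 of 20 higher and 1 lower, NF-kB genes 5 of 25 higher and 0 lower and interferon-stimulated genes 0 of 39 higher and 6 lower (median -0.22). The highest included Ccser1 (4.82, 3.81 to 6.08), U90926 (4.33, 3.81 to 4.92), Slc7a11 (3.97, 3.64 to 4.34), Ptgs2 (3.82, 3.64 to 4.0) and Slc7a2 (3.52, 3.35 to 3.71). The cytokines Il1a (3.3, 2.86 to 3.81), Il6 (2.73, 2.35 to 3.17), Il1b (2.58, 2.53 to 2.63), Il19 (2.93, 2.45 to 3.51) and Tnf (1.95, 1.9 to 2.0) and the chemokine Cxcl2 (3.09, 3.01 to 3.18) were higher. The feedback genes Traf1 (2.2, 2.04 to 2.38) and Tnfaip3 (2.07, 1.99 to 2.16) were higher too. The lowest were Ccnd1 (0.355, 0.33 to 0.382), Fat3 (0.381, 0.35 to 0.416), Ifit1bl1 (0.419, 0.384 to 0.457), Adra1a (0.423, 0.381 to 0.468) and Pdgfc (0.441, 0.387 to 0.503). Ifit2 (0.518, 0.506 to 0.531), Rsad2 (0.60, 0.593 to 0.607) and Ccl7 (0.469, 0.463 to 0.475) were lower too. N4bp1 (1.23, 1.2 to 1.26), Nfkbia (1.19, 1.18 to 1.21), Ikbke (1.02, 0.994 to 1.05), Tbk1 (1.05, 1.01 to 1.09) and Casp8 (0.90, 0.864 to 0.938) lay within 1.5-fold. Chemokines divided (5 of 16 higher and 4 lower). The genes Cxcl3 (4.19, 3.52 to 4.99), Cxcl1 (2.63, 2.37 to 2.93) and Il12b (2.08, 1.87 to 2.3) stood at 7.72, 4.01 and 3.22 without cells near the reporter threshold, and Tnfsf15 (2.77, 1.81 to 4.25) stood at 1.25 in thinned cells. Igkc (54.9, 31.3 to 96.3) stood at 19.8 without the largest cell of each of the 4 populations, 11.8 with a minimum of 1000 UMIs per droplet and 227 without clusters led by other cell types.

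Unstimulated, the same ratio of ratios set interferon-stimulated genes apart in the other direction (3 of 36 higher and 0 lower). The shift lies in the GFP+ cells (median -0.39 log2), not in KO over WT GFP- cells (0 of 36 higher and 0 lower, median -0.08). Of their members 33 lay above the median of all genes, with Isg20 (2.0, 1.62 to 2.47), Ifi44 (1.73, 1.44 to 2.08) and Isg15 (1.52, 1.43 to 1.61). The largest single values were Cxcl10 (4.82, 4.34 to 5.35), Tmem176a (2.29, 2.08 to 2.52), Ltf (2.57, 2.2 to 3.02) and Camp (2.99, 2.62 to 3.41). The lowest were Ccl7 (0.302, 0.273 to 0.335), Gdf15 (0.342, 0.294 to 0.397), Pdpn (0.402, 0.345 to 0.468), Nptx1 (0.413, 0.374 to 0.456) and Plau (0.455, 0.421 to 0.493). NF-kB genes had 3 of 24 higher and 0 lower with Traf1 (1.71, 1.33 to 2.2), Relb (1.56, 1.42 to 1.72), Nfkbie (1.55, 1.31 to 1.82) and chemokines 2 of 13 higher and 5 lower. Csmd1 (1188, 668 to 2115) rests on 1 cell in each of 2 populations, with 714 of 729 UMIs in KO cells and 809 of 827 in GFP+ cells beside WT cells. Without the largest cell of each population it stood at 0.845. Cxcl10 stood at 2.19 in thinned cells, Camp at 5.28, and Ltf at 5.03. Ccl12 (2.66, 2.18 to 3.24) and Cxcl2 (0.453, 0.37 to 0.556) stood at 1.35 and 0.89 in thinned cells, and at 0.638 and 0.998 without the largest cell of each population. With a reporter threshold of 1 UMI Ccl7 stood at 1.01 and Pdpn at 0.639.

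**Figure D3:**
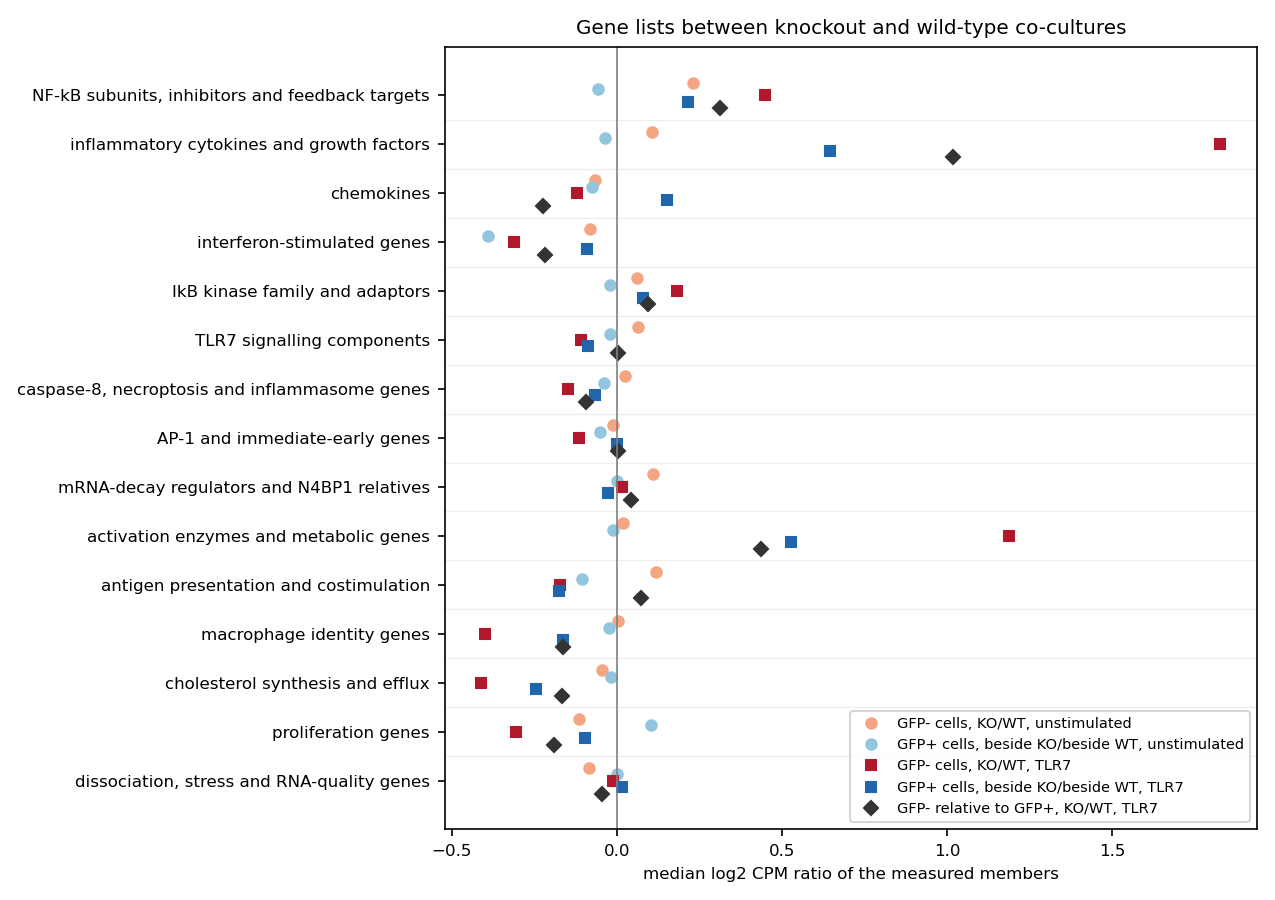
Median log2 CPM ratio of the measured members of each of the 15 gene lists in 5 comparisons. After stimulation the cytokine list lies at 1.83 in KO over WT cells and at 0.64 in GFP+ cells beside KO over beside WT cells, and the interferon-stimulated list at -0.31 and -0.09.

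The response to TLR7 in KO cells, divided by that in WT cells, was larger for most cytokines and part of the NF-kB genes and smaller for part of the interferon-stimulated genes, and early-response genes divided. Cytokines had 11 of 14 higher and 0 lower, NF-kB genes 6 of 25 higher and 0 lower and early-response genes 7 of 20 higher and 4 lower (9 higher and 2 lower with TMM scaling). Chemokines had 6 of 16 higher and 3 lower and metabolic genes 10 of 20 higher and 3 lower. Interferon-stimulated genes had 1 of 39 higher and 7 lower (1 higher and 4 lower with TMM scaling) and antigen presentation genes 1 of 18 higher and 3 lower (1 higher and 1 lower with TMM scaling). The largest ratios were Serpinb2 (32.7, 13.2 to 81.3), Il1b (28.3, 18 to 44.5), Ptgs2 (21, 12.3 to 35.9), Cxcl1 (18.6, 11.4 to 30.2), Cxcl2 (17.5, 15 to 20.5) and Slc7a2 (8.48, 6.99 to 10.3). Il6 had 0 UMIs in unstimulated KO and 3 in unstimulated WT cells. With the 0 set to the floor its ratio is a bound of at least 14.7 (2.96 to 73.2 with the floor taken as a count). Without the largest cell of each population the bound was 5.04. Tnfaip3 (4.19, 3.73 to 4.7), Nlrp3 (3.12, 2.93 to 3.32), Egr1 (3.55, 2.84 to 4.43), Fosl2 (2.85, 2.56 to 3.18) and Tnf (2.9, 2.63 to 3.19) were larger as well. Smaller in KO cells were Ifit2 (0.445, 0.417 to 0.475), Ifit3 (0.499, 0.467 to 0.533), Mertk (0.352, 0.325 to 0.381) and Irf5 (0.453, 0.431 to 0.476). So were Hpgd (0.155, 0.0955 to 0.252), Slco2b1 (0.0706, 0.00932 to 0.535), with 1 UMI in stimulated KO cells, Tpt1-ps3 (0.0661, 0.0568 to 0.0769) and Rps19-ps6 (0.154, 0.131 to 0.181). N4bp1 (1.12, 1.05 to 1.18), Nfkbia (1.17, 1.12 to 1.22), Ikbke (0.869, 0.819 to 0.922), Tbk1 (1.06, 1.02 to 1.12) and Casp8 (0.845, 0.80 to 0.892) lay within 1.5-fold. Acod1 (0.292, 0.169 to 0.506) was smaller too, over 14 UMIs in unstimulated WT cells, although its stimulated level was higher in KO (1339.7 CPM) than in WT cells (611 CPM). Several of these rest on few unstimulated UMIs. Serpinb2 rests on 6 in KO cells, and stood between 10.2 and 68.3 where an alternative left 0 UMIs in 1 population. Igkc, with 0 UMIs in unstimulated WT cells and 65.6% of stimulated KO UMIs in 1 cell, is not read here. Without the largest cell of each population Ptgs2 stood at 11, Cxcl1 at 12 and Cxcl2 at 9.04. Il1b stood at 14.1 and Traf1 (2.03, 1.68 to 2.46) at 1.31 in thinned cells, and H2-Eb1 (0.639, 0.557 to 0.733) at 0.978 without clusters led by other cell types. With a reporter threshold of 1 UMI Il1b stood at 49.8, Cxcl1 at 35.3 and Acod1 at 0.141. Hpgd stood at 0.565 without clusters led by other cell types. Lox (0.149, 0.0197 to 1.13) rests on 1 unstimulated WT UMI.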

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

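The tests in this part were chosen only after the results were seen. Among 392 named genes and list members in 4 pairs of comparisons, 11 times a gene was higher in one comparison and lower in its partner, and none of these differences was tested. Between the response to TLR7 in WT and in KO cells these were Tpt1-ps3 (1.99, 1.81 to 2.21, against 0.132, 0.117 to 0.148) and mt-Atp6 (0.618, 0.603 to 0.633, against 1.86, 1.82 to 1.91). Between KO over WT unstimulated and stimulated they were Ccl4 (0.655, 0.633 to 0.677, against 1.62, 1.61 to 1.63), Cxcl2 (0.565, 0.483 to 0.66, against 9.91, 9.71 to 10.1), Dennd2a (1.91, 1.73 to 2.11, against 0.461, 0.423 to 0.502), Rpl3-ps1 (1.74, 1.59 to 1.91, against 0.422, 0.386 to 0.461), Tmem51 (1.56, 1.45 to 1.68, against 0.614, 0.578 to 0.653), Tpt1-ps3 (2.48, 2.24 to 2.74, against 0.164, 0.146 to 0.183) and mt-Atp6 (0.635, 0.619 to 0.652, against 1.92, 1.88 to 1.95). Between unstimulated KO over WT cells and unstimulated GFP+ cells beside KO over beside WT cells they were Csmd1 (20.3, 13.7 to 31.3, against 0.0171, 0.0106 to 0.026) and Gdf15 (0.623, 0.566 to 0.686, against 1.82, 1.62 to 2.05).

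Tpt1-ps3, Rpl3-ps1 and mt-Atp6 belong to features that pair the WT unstimulated with the KO stimulated library against the other pair, in GFP- and GFP+ cells alike: Tpt1-ps3 stood at 11.9, 29.5, 23.8 and 3.9 CPM in GFP- cells and at 13.6, 32.1, 23.2 and 4.36 CPM in GFP+ cells. Genotype of the GFP- cells predicts a crossed ratio near 0 in GFP+ cells, but over 50 other features with a pseudogene name (-ps) the median log2 crossed ratio was -0.34 there, and the GFP- minus GFP+ difference was -0.10. With each cell thinned to one depth, the median in GFP+ cells was -0.29. Thinning evens the weight of cells but keeps the expected proportions within each, so other effects of UMI depth stay undecided. That reads of pseudogenes and their parent genes were divided differently between libraries predicts a low median for the pseudogenes and not for their parents, and the 39 parents measured had 0.14. The pseudogene values go with that last explanation, but the counts alone cannot show it. In GFP+ cells the protein-coding genes Gpx4 (251, 226, 92.3 and 26.9 CPM) and Rpl10 (1634, 1467, 716 and 327 CPM) also fell further with stimulation in the KO library. The test over pseudogenes covers neither these genes nor mt-Atp6.

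GFP+ WT cells beside KO cells held more transcripts of most cytokines after stimulation than those beside WT cells. GFP- RNA or cells mixed into the GFP+ pool could raise them, and Gm28438, a feature high in GFP- and low in GFP+ cells, sets the mixed share at 10.9% (7.13 to 16.1%) if all of it in GFP+ cells came from GFP- cells. That bound rests on 309 UMIs in GFP- and 28 in GFP+ cells of the stimulated KO library. Gm28438 itself stood at 3.4 CPM in GFP- cells there, against 42.3 CPM in the stimulated WT library. Why it fell was not tested, so the bound is itself uncertain. Of the 14 cytokine, chemokine, metabolic and NF-kB genes at least 4.11-fold higher in KO cells than in GFP+ cells beside WT cells, the least at which mixing at that upper bound lifts a gene to 1.5-fold, 10 need more than the bound even at the lower limit of their counting interval, and Il12b, Il19, Cxcl3 and Slc7a11 do not (share needed: median 21.4%, 15.4 to 38.8%), so mixing is not excluded for the pattern as a whole. With each cell thinned to one depth, 7 of 13 cytokines were higher against 8 before, so the weight of deep cells alone does not give the pattern. Thinning keeps the expected proportions within each cell, so other effects of the lower depth in that library stay undecided. With 1 pair of stimulated cultures, an effect of the neighbours cannot be told apart from another difference between the cultures, or from mixing in part.

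Stimulated KO cells held fewer transcripts of part of the interferon-stimulated genes while cytokine transcripts were higher. Scaling to total UMIs, which abundant cytokine transcripts raise, could lower the others, but with TMM scaling the list's median was still -0.21 log2. A difference between the cultures that acts on both populations predicts a median near 0 relative to GFP+ cells of the same library, and it was -0.22. With 1 KO culture per condition, N4bp1 cannot be told apart from other differences between the bone marrow donors.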

How the results depend on the processing

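The alternative that leaves out, for each gene, the largest single cell of each population was chosen only after the results were seen; the other 12 were planned. No paired analysis was possible because no group has replicate libraries, and no result comes from a test. GFP- and GFP+ cells of the same library are compared as a ratio of ratios. Of the values that answer a comparison, 253 kept their level across alternatives and 27 moved; of the other values, of single genes and lists, 7646 kept it, 1592 moved beyond their counting interval, and 10 turned around. The limit of 10% mitochondrial UMIs moved nothing. The counting intervals are narrow in populations of this depth, so small shifts count as moved. With the 2-fold rule and with no filter on low counts the counts differ by construction; for the other values below, apart from Lox, the cause was not tested.

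Against 46.7, 49.1, 51.5 and 44.8% GFP+ cells in the main run (WT unstimulated, KO unstimulated, WT stimulated, KO stimulated), a minimum of 1000 UMIs per droplet gave 42, 46, 49.2 and 42.5%, a reporter threshold of 1 UMI 61, 62.2, 60.6 and 52.6%, and leaving out cells near the threshold 39.98, 42.8, 48.1 and 33.6%; with no doublets removed the stimulated KO library had 46.2%. N4bp1 in KO over WT cells stood at 1.6 stimulated with TMM scaling and at 1.22 unstimulated in thinned cells. Interferon-stimulated genes lower in GFP+ cells beside KO cells after stimulation numbered 1 with no doublets removed and 1 with a reporter threshold of 1 UMI, against 0. In unstimulated KO over WT cells 1 was lower with the mean of per-cell CPM and 1 in thinned cells, against 0. In the response of KO relative to WT cells 4 were lower with TMM scaling, against 7. With the 2-fold rule the lower interferon-stimulated genes numbered 3 in stimulated KO over WT cells (against 9), 0 in unstimulated GFP+ cells (against 5), 0 in the stimulated ratio of ratios (against 6) and 2 in the response of KO relative to WT cells (against 7), and the higher cytokines in stimulated GFP+ cells 4 (against 8). With no filter on low counts the higher cytokines numbered 3 in unstimulated KO over WT cells and 5 in the unstimulated ratio of ratios, against 0.

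Ratios that turned around were Ccl5 in unstimulated GFP+ cells (1.73 to 0.516 with a minimum of 1000 UMIs per droplet and 0.315 without cells near the reporter threshold). In the unstimulated ratio of ratios, Csmd1 (1188) stood at 0.41 with a reporter threshold of 1 UMI, 0.998 without clusters led by other cell types and 0.845 without the largest cells, Ccl7 (0.302) at 1.01 with a reporter threshold of 1 UMI, and Ccl12 (2.66) at 0.638 without the largest cells. In the response of KO relative to WT cells, Lox (0.149) stood at 1.24 with a reporter threshold of 1 UMI, 3.27 in thinned cells and 1.12 without the largest cells; in all 3 its single unstimulated WT UMI is gone and the floor of 3 UMIs sets the value.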

Other observations

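In this part the test across single cells was chosen before its result was seen. GFP+ cells, too, answered TLR7 with cytokine (11 of 11 beside WT cells and 13 of 13 beside KO cells higher), interferon-stimulated (39 of 39 and 39 of 39) and metabolic genes (19 of 19 and 20 of 20). Beside WT cells the ratios included Saa3 (5752, 4837 to 6894), Socs3 (439.7, 306 to 657) and Tnf (9.18, 8.55 to 9.86), and beside KO cells Saa3 (1705, 1589 to 1832), Cd38 (1097, 613 to 2198) and Tnf (14.3, 13.5 to 15.1). Cell-cycle genes were lower in both (21 of 22 and 21 of 22).

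GFP- and GFP+ WT cells of the same library also differed without any difference in N4bp1. Unstimulated, Pdpn (3.15, 2.8 to 3.57), Gdf15 (2.25, 2.0 to 2.55) and the elastase Mmp12 (1.96, 1.92 to 2.01) were higher and Cxcl10 (0.24, 0.224 to 0.258), Erdr1 (0.306, 0.286 to 0.327) and mt-Nd3 (0.22, 0.204 to 0.238) lower in GFP- cells. Stimulated, Mmp9 (2.45, 2.27 to 2.65), Plac8 (2.32, 2.13 to 2.53), Gria3 (2.22, 2.05 to 2.42) and F13a1 (2.07, 1.91 to 2.25) were higher and mt-Nd3 (0.152, 0.138 to 0.166), Erdr1 (0.277, 0.261 to 0.293) and Wwc2 (0.512, 0.481 to 0.544) lower, and 21 of 21 cell-cycle genes lay above the median of all genes (median 0.31 log2). Gm28438, chosen after its values were seen, stood at 84.5, 109, 42.3 and 3.4 CPM in GFP- cells and 12.7, 7.53, 4.06 and 0.371 CPM in GFP+ cells (WT unstimulated, KO unstimulated, WT stimulated, KO stimulated). The Y-linked gene Ddx3y stood at 56.9 to 81.2 CPM in all 8 populations, and Xist had at most 2 UMIs in any of them. Of the other genes listed as able to differ between donor mice, Wdfy1 stood at 42.8 to 62.7 CPM in GFP- and 26.6 to 35.5 CPM in GFP+ cells. Ide stood at 18.2 to 36.2 CPM in GFP- and 26.4 to 54.2 CPM in GFP+ cells. In every library Wdfy1 was above in GFP- and Ide in GFP+ cells. Nnt and Entpd4 stayed below 5 CPM.

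A hypothesis tested across single cells was that KO cells high in cytokine transcripts are those low in interferon-stimulated transcripts. It predicts a Spearman's rho below -0.1 between the UMI sums of these lists in stimulated KO cells thinned to one depth, and rho was 0.0199 over 7366 cells. The prediction was not borne out by this measure, but free RNA adds UMIs of both lists to every cell and was not removed, and abundant members weigh most in the sums. Over all libraries 1 cluster was led by Cxcl10, Rsad2 and Ccl7 and another by Ptgs2, Cxcl2 and Il1b. How KO cells divide between these clusters is not given here. In the other stimulated populations rho was 0.133 (WT cells), 0.102 (GFP+ cells beside WT cells) and 0.104 (GFP+ cells beside KO cells).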
